A study of Mus musculus with 12 samples.

How the data were processed

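RNA of 12 cultures of mouse satellite cell-derived myoblasts was measured on Affymetrix expression arrays, 1 array per culture. Per the labels, total RNA was extracted with Trizol and 215 ng was labelled with biotin using the Ambion WT Expression kit. The deposited table holds log2 values that the authors made with RMA in Affymetrix Expression Console, versions not stated. RMA corrects background, brings the arrays to a common distribution and summarises the probes of each row. The values ran from 2.00 to 14.50 and the array medians from 7.312 to 7.402, and they were used as deposited, with no further normalization and no filter. The number of arrays, 3 per construct, limits the precision, and the median standard error of a log2 fold change was 0.0647.

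The table has 35556 rows. The probe table lists 23410 of them, 21789 with exactly 1 gene and 1621 with several, and leaves out 12146. Only rows with exactly 1 gene were tested, and the 999 genes with more than 1 such row were represented by the row with the highest mean, which gave 19938 genes. The gene identifiers of 21698 single-gene rows were found in the mouse reference, which changed 0 symbols. No row was matched to a position on a chromosome.

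Groups and mice came from the labels, which number the mice 1 to 3 and state that sister cultures of each mouse received the constructs. One linear model with construct and mouse was fitted per gene to all 12 arrays with limma 3.58.1 in R 4.3.3, followed by eBayes (6 residual degrees of freedom, prior degrees of freedom 3.11). The 5 comparisons were each construct against control, Pax7 against Pax7-ERD and PAX7-FOXO1A against Pax7. A gene was called when its p, adjusted by the method of Benjamini and Hochberg over all genes of the comparison, was under 0.05, with no minimum fold change. Residuals of arrays from the same mouse correlated with a mean of 0.0314 over 18 pairs (range -0.224 to 0.515), and 4 of 12 arrays correlated best with an array of their own mouse. The pairing therefore rests on the labels, and each count of called genes is also given without the mouse as a block. Correlations between arrays were 0.994 to 0.997 within groups (12 pairs) and 0.980 to 0.994 between groups (54 pairs).

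The 24 lists comprised 18 gene lists and 6 lists of markers of other cell types. The gene lists were muscle differentiation and contractile, satellite cell and myoblast identity, Notch, BMP response and Id, PAX-FOXO1 rhabdomyosarcoma, FOXO targets, G1/S and DNA replication, G2/M and mitosis, p53, interferon, hypoxia and glycolysis, NRF2, oxidative phosphorylation, RTK-MAPK feedback and targets, TGF-beta, Wnt, extracellular matrix and adhesion, and neural lineage and axon guidance. The marker lists were fibroblast, endothelial, macrophage and leukocyte, adipocyte, Schwann and glial, and pericyte and smooth muscle. Each list was tested with limma's camera, which compares its genes with all others, at a preset correlation between genes of 0.01, adjusted over the 24 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Lists share up to 3 genes in pairs, such as the TGF-beta and extracellular matrix lists.

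The comparisons, lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Pax7, Foxo1, Pax3, Myf5, Myod1, Myog, Id3 and Fgfr4, and then the 8 highest and 8 lowest log2 fold changes of a comparison (5 and 5 for Pax7 against Pax7-ERD). Those genes had to be called, to move the same way in 3 of 3 mice, and to have a mean of at least log2 7.21 (40th percentile of all genes) in the brighter group. Symbols of predicted genes were left out of that ranking. Further, the rule takes up to 4 called members with the lowest p of each list that passed, up to 2 of any other list, and up to 8 genes per direction for each pair of comparisons with shared calls. Shared calls were set beside the count that independent lists would give and beside 20 simulations in which all arrays, controls included, were drawn with no change.

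The alternatives were no mouse block, the 6 arrays of a comparison alone, quantile normalization, median centring per array, dim genes left out (mean below log2 6.60, 30th percentile), the mean of a gene's rows, all rows of the table, trended and robust variance, array weights, a minimum log2 fold change of 1, and leaving out each mouse and each array in turn. On data simulated for Pax7 against control over 19938 genes, the same model recovered 13 of 50 changed genes at a log2 change of 0.25, 44 of 50 at 0.5 and all 50 at 1. Only 50 genes were changed at each size, whereas 5535 were called in the data, so the adjusted threshold was stricter in the simulation. The recovery of small changes there does not carry over to the data, where the smallest called log2 change was 0.111. Of 169 calls in that simulation 12 were false, and with no change added at most 1 gene was called in 10 repeats. A list of 21 genes shifted by 0.4 was called in 10 of 10 repeats, but genes were drawn independently of each other there. That recovery does not carry over to lists whose genes are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.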

Results

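Expression arrays measured RNA in 12 cultures of mouse myoblasts, the dividing muscle precursor cells that descend from satellite cells, the stem cells of skeletal muscle. The cells came from hindlimb muscle of 3 male C57Bl/10 mice and were expanded for 6 days. Each mouse gave 4 sister cultures, and each culture was infected with a different retrovirus and grown for another 48 hours. The groups of 3 arrays each were a control virus, Pax7, Pax7-ERD (named dominant-negative in the labels) and PAX7-FOXO1A. Pax7 is a transcription factor of satellite cells, and a fusion of PAX7 with FOXO1 is found in alveolar rhabdomyosarcoma, a childhood muscle tumour. Signals are log2 values, with array medians between 7.312 and 7.402, and the number of arrays limits the precision. Changes are log2 fold changes ± standard error with n = 3 per group, adjusted p values come from limma, and "higher" or "lower" counts refer to genes with adjusted p under 0.05. Movement in the same direction in 3 of 3 mice was a condition for naming the genes of the largest changes. The mean of every list that passed its test also moved the same way in 3 of 3 mice. Most lists that did not pass also moved in the direction of their test in 3 of 3 mice. This agreement therefore does not set the passed lists apart.

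The row of Pax7 (10517715) read 11.29 ± 0.06 (SD, n = 3) in control, 13.36 ± 0.01 with Pax7 and 13.02 ± 0.05 with Pax7-ERD. In the arrays labelled PAX7-FOXO1A it read 11.31 ± 0.05, and the row of Foxo1, a forkhead transcription factor, read 10.98 ± 0.05 against 11.04 ± 0.01 in control. Neither row was raised there, so neither serves as a check of the fusion, and the identity of those arrays rests on the labels. Myf5, a myogenic regulator of dividing myoblasts, read 9.65 ± 0.05 in control, 11.69 ± 0.11 with Pax7, 8.63 ± 0.07 with Pax7-ERD and 10.33 ± 0.08 with PAX7-FOXO1A. The first principal component held 48.0% of the variance and set the PAX7-FOXO1A arrays apart. The second held 33.9% and separated Pax7 from Pax7-ERD, with the control arrays between them.

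**Figure D1:**
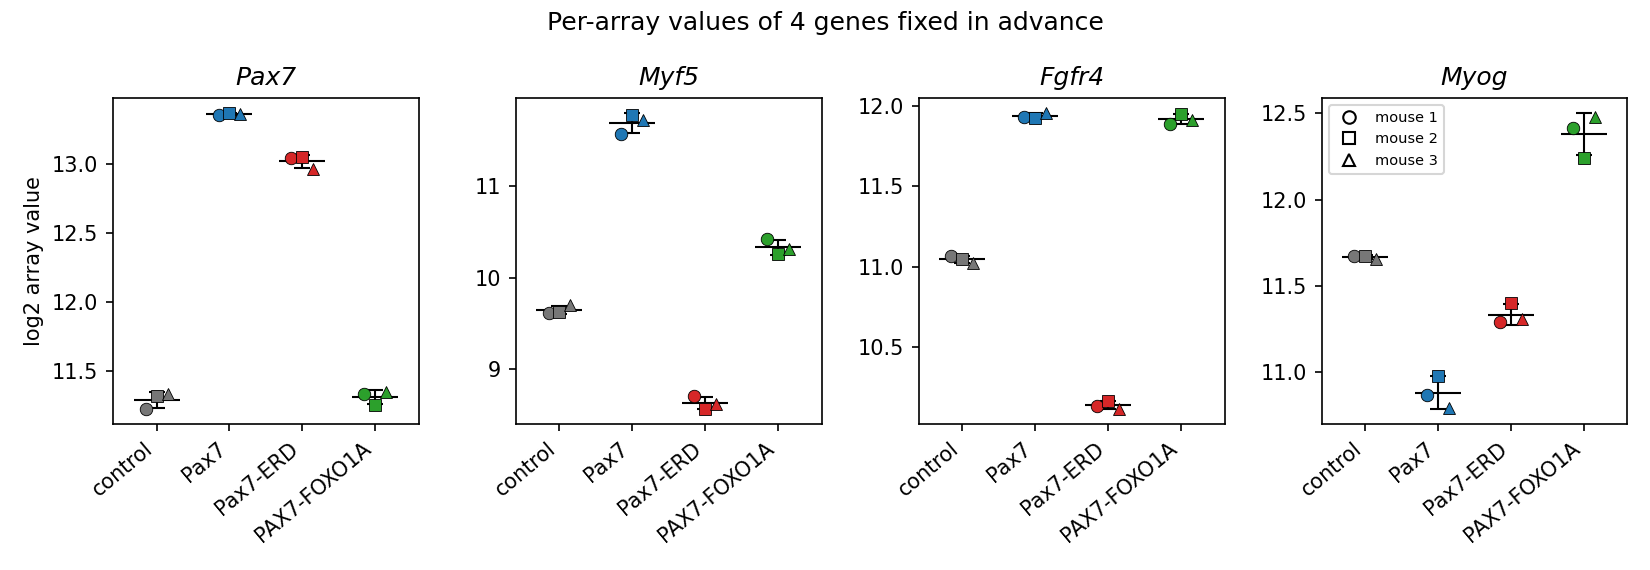
Log2 signal of Pax7, Myf5, Fgfr4 and Myog in each of the 12 arrays, by construct, with marker shape for the mouse and bars for the mean ± SD (n = 3). Myf5 lies above control with Pax7 and PAX7-FOXO1A and below it with Pax7-ERD, while Myog is lowest with Pax7 and highest with PAX7-FOXO1A.

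Pax7 against control asks how myoblasts respond to added Pax7. The cultures with Pax7 held less RNA of muscle differentiation genes and more of cell cycle genes, though the G2/M list lost its call with the correlation estimated (adjusted p = 0.0751 with an estimated correlation). Myf5 rose 4.11-fold (2.04 ± 0.07, adjusted p = 6.82e-08), and Fgfr4, a fibroblast growth factor receptor of myogenic cells, rose 1.86-fold (0.89 ± 0.04, adjusted p = 2.43e-07). Myog, the regulator that starts terminal differentiation, fell 1.73-fold (-0.79 ± 0.07, adjusted p = 3.12e-05). The largest increase was that of Itga2, the alpha subunit of a collagen-binding integrin, at 16.1-fold (4.005 ± 0.05, adjusted p = 1.03e-09). The largest decrease was that of Gzmd, a granzyme protease, at 13.8-fold (-3.79 ± 0.08, adjusted p = 5.03e-09).

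Among the other increases were Vat1l (3.63 ± 0.06), the calcium-dependent phosphodiesterase Pde1a (3.61 ± 0.06), the olfactory receptor pseudogene Olfr1372-ps1 (3.48 ± 0.13) and Tshr, the thyrotropin receptor (3.47 ± 0.06). Mme, the cell surface peptidase neprilysin (3.45 ± 0.06), the growth factor Bmp4 (3.17 ± 0.08) and Zfp185 (3.12 ± 0.05) completed the 8 highest. The other decreases were those of Gzme (-3.03 ± 0.14), the cytokine Il11 (-2.93 ± 0.06), the protease inhibitor Serpinb2 (-2.75 ± 0.06) and Igfbp2, a binding protein of insulin-like growth factors (-2.49 ± 0.05). Akr1c18, a steroid dehydrogenase (-2.42 ± 0.11), the gap junction gene Gja5 (-2.26 ± 0.06) and the water channel Aqp1 (-2.25 ± 0.07) also fell. Foxo1 rose by 0.38 ± 0.04 (adjusted p = 0.00012), while Pax3, the paralog of Pax7, read 0.11 ± 0.06 (adjusted p = 0.209) and Id3, an inhibitor of myogenic factors, 0.04 ± 0.08 (adjusted p = 0.767). Myod1, the myoblast determination factor, fell by 0.12 ± 0.04 (adjusted p = 0.0425), and this call ended in 10 of 17 alternatives (adjusted p 0.000273 to 0.300).

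Of 50 muscle differentiation and contractile genes, 45 fell and 1 rose (median -0.82, adjusted p = 4.18e-31, and 0.0154 with an estimated correlation). Among them were Xirp1, an actin-binding protein of myofibrils (-1.74 ± 0.05), Myh1, a fast myosin heavy chain (-1.44 ± 0.05), the sarcomere protein gene Myom1 (-1.17 ± 0.04) and the calcium channel gene Cacna1s (-1.10 ± 0.04). The G1/S and DNA replication list had 32 of 35 genes higher and 1 lower (median 0.45, adjusted p = 4.27e-16, and 0.0463 with an estimated correlation). It includes the thymidine kinase gene Tk1 (0.68 ± 0.04), cyclin E1, Ccne1 (0.63 ± 0.04), and the DNA ligase gene Lig1 (0.58 ± 0.05). All 39 measured G2/M genes rose (median 0.42, adjusted p = 1.80e-21), with the kinetochore genes Ndc80 (0.62 ± 0.04) and Nuf2 (0.55 ± 0.04) and the checkpoint kinase gene Bub1b (0.54 ± 0.05) among them. That call was lost with an estimated correlation (adjusted p = 0.0751 with an estimated correlation).

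Of 21 TGF-beta response genes, 19 fell and 1 rose (median -0.52, adjusted p = 1.63e-13, but adjusted p = 0.0751 with an estimated correlation). Ltbp2, which encodes a latent TGF-beta binding protein (-1.29 ± 0.06), the protease inhibitor Timp3 (-1.25 ± 0.05), the collagen cross-linking enzyme Lox (-1.20 ± 0.05) and the ligand Tgfb2 (-0.84 ± 0.05) were among the decreases. Of 40 extracellular matrix and adhesion genes, 25 fell and 3 rose (median -0.23, adjusted p = 9.01e-09, but adjusted p = 0.135 with an estimated correlation), with the matrix genes Fbln2 (-1.08 ± 0.04), Nid2 (-0.99 ± 0.05) and Thbs2 (-0.76 ± 0.04) as examples. Markers of 2 other cell types moved with these groups. Of 14 pericyte and smooth muscle markers, 10 fell and none rose (median -0.33, adjusted p = 3.74e-07, and 0.0154 with an estimated correlation), including Cspg4 (-1.21 ± 0.05), Cnn1 (-1.19 ± 0.07) and Abcc9 (-1.01 ± 0.05). Of 16 fibroblast markers, 7 fell, such as Mfap5 (-1.35 ± 0.06), and 2 rose, such as Fap (1.54 ± 0.11). The fibroblast test gave adjusted p = 0.0378, adjusted p = 0.135 with an estimated correlation, and a range of 0.0205 to 0.0546 over the other camera settings. It passed 0.05 without mouse 3 (0.0519), without control mouse 2 (0.0546) and without Pax7 mouse 1 (0.0520).

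The RTK-MAPK feedback and target list, genes that receptor tyrosine kinase signalling induces, had 14 of 22 genes lower and 4 higher (median -0.23, adjusted p = 7.58e-05, but adjusted p = 0.254 with an estimated correlation). Hbegf, a ligand of the EGF receptor (-1.52 ± 0.06), the ephrin receptor gene Epha4 (-1.20 ± 0.06) and the phosphatase genes Dusp5 (-0.91 ± 0.05) and Dusp4 (-0.62 ± 0.05) fell. The neural lineage and axon guidance list had 18 of 40 genes lower and 6 higher (median -0.13, adjusted p = 0.0128, but adjusted p = 0.135 with an estimated correlation). Its members with the smallest p include Nrp1, a semaphorin co-receptor (-0.86 ± 0.04), and Ncam1, an adhesion molecule that muscle cells also carry (-0.64 ± 0.04), while Efnb2, an ephrin ligand, rose (0.59 ± 0.04). Adjusted over the list alone, the higher and lower counts were 1 and 46 for muscle differentiation, 4 and 15 for RTK-MAPK, 4 and 27 for extracellular matrix, 8 and 18 for neural lineage and 1 and 11 for pericyte markers. For the G1/S, G2/M, TGF-beta and fibroblast lists, the counts adjusted over the list alone equalled those over all genes.

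The other 15 lists did not pass in this comparison. Of 31 satellite cell and myoblast identity genes, 6 rose and 13 fell (adjusted p = 0.403), and the Notch list had 3 higher and 7 lower of 22 (adjusted p = 0.478), including the ligand Jag1 (-1.01 ± 0.05). The BMP and Id list had 5 higher and 8 lower of 21 (adjusted p = 0.653), with Bmp6 at 1.84 ± 0.08, and the PAX-FOXO1 rhabdomyosarcoma list 8 higher and 7 lower of 29 (adjusted p = 0.712). The Wnt list had 5 higher and 6 lower of 21 (adjusted p = 0.839), with the R-spondin receptor gene Lgr5 at 2.94 ± 0.05 and the Wnt receptor gene Fzd4 at 1.42 ± 0.08. The FOXO target (adjusted p = 0.463), p53 (0.201), interferon (0.0644), hypoxia and glycolysis (0.158), NRF2 (0.712) and oxidative phosphorylation (0.138) lists did not pass either. The remaining marker lists gave adjusted p = 0.872 for endothelial cells, 0.216 for macrophages and leukocytes, 0.958 for adipocytes and 0.712 for Schwann and glial cells. Median, mean and camera direction differed in sign for the satellite cell, BMP, PAX-FOXO1, Wnt, endothelial and adipocyte lists.

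limma with the mouse as a block called 5535 of 19938 genes, 2839 higher and 2696 lower (2765 and 2783 with each array centred on its median), and 371 of them had an absolute log2 fold change of at least 1, of which 169 were higher and 202 lower. Without the mouse block 5551 genes were called, 5319 of them shared with the blocked result. Leaving out mouse 1 or mouse 2 lowered the count to 3564 or 3553. Camera with a preset correlation also called up to 8 of the 24 lists on splits that mixed the groups, beside 9 on the real one.

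Pax7-ERD against control asks how myoblasts respond to the dominant-negative construct. These cultures held less RNA of cell cycle genes and more of matrix, TGF-beta and hypoxia genes. Myf5 fell 2.02-fold (-1.01 ± 0.07, adjusted p = 1.68e-05) and Fgfr4 fell 1.87-fold (-0.90 ± 0.04, adjusted p = 1.33e-06). The largest increases were those of Nt5e, the ectonucleotidase CD73, at 10.8-fold (3.43 ± 0.05, adjusted p = 1.10e-09), and of F3, tissue factor, which starts blood coagulation, at 8.27-fold (3.05 ± 0.09, adjusted p = 3.15e-07). Decreases were smaller, the largest being Rgs5, a regulator of G protein signalling, at 2.32-fold (-1.21 ± 0.06, adjusted p = 2.64e-06).

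The other highest genes were Wfdc2 (2.94 ± 0.10), the annexin gene Anxa8 (2.56 ± 0.09), the cytokine gene Tslp (2.39 ± 0.09), the matrix proteoglycan gene Prelp (2.18 ± 0.06), the phospholipid scramblase gene Plscr2 (2.09 ± 0.07) and the purinergic receptor gene P2ry14 (2.01 ± 0.07). Besides Rgs5 and Myf5, the lowest were the cytokine gene Il33 (-1.21 ± 0.07), the carboxypeptidase gene Cpa5 (-1.09 ± 0.06), the heparan sulfate enzyme gene Ndst4 (-1.05 ± 0.11), the neuropeptide gene Gal (-1.05 ± 0.04), Lix1 (-1.003 ± 0.09) and the kinase gene Rps6ka6 (-0.98 ± 0.09). Pax3 read 0.13 ± 0.06 (adjusted p = 0.169) and Id3 -0.11 ± 0.08 (adjusted p = 0.442). Myog fell by 0.34 ± 0.07 (adjusted p = 0.00956, range 3e-04 to 0.133), a call that ended without mouse 1 (0.133) and without mouse 3 (0.0503). Foxo1 fell by 0.21 ± 0.04 (adjusted p = 0.00658, range 9.11e-05 to 0.101), a call that ended whichever mouse was left out. Myod1 fell by 0.15 ± 0.04 (adjusted p = 0.0185, range 2.35e-05 to 0.180), and that call ended in 10 of 17 alternatives.

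Of 35 G1/S and DNA replication genes, 34 fell and none rose (median -0.43, adjusted p = 1.90e-23, and 0.0217 with an estimated correlation), with Dtl (-0.63 ± 0.06), the DNA polymerase gene Pole (-0.54 ± 0.05) and Ccne1 (-0.52 ± 0.04) among them. Of 39 G2/M genes, 38 fell and none rose (median -0.42, adjusted p = 8.33e-27, and 0.0467 with an estimated correlation), including Nuf2 (-0.60 ± 0.04), Bub1b (-0.60 ± 0.05) and the topoisomerase gene Top2a (-0.56 ± 0.05, and -0.191 in its other, dimmer row). The hypoxia and glycolysis list had 14 of 24 genes higher and 1 lower (median 0.27, adjusted p = 2.98e-10, and 0.00837 with an estimated correlation). The lactate exporter gene Slc16a3 (0.86 ± 0.04), the collagen prolyl hydroxylase gene P4ha2 (0.60 ± 0.04), the glucose transporter gene Slc2a1 (0.57 ± 0.04) and the angiogenic factor gene Vegfa (0.54 ± 0.04) rose.

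The matrix and TGF-beta lists rose. Of 40 extracellular matrix and adhesion genes, 28 were higher and 1 lower (median 0.23, adjusted p = 1.95e-14, and 0.0467 with an estimated correlation), including Col12a1, a fibril-associated collagen (0.79 ± 0.04), Fbln2 (0.73 ± 0.04) and the laminin gene Lamc1 (0.56 ± 0.04). Of 21 TGF-beta response genes, 18 were higher and 1 lower (median 0.38, adjusted p = 2.69e-13, and 0.0467 with an estimated correlation), including Ltbp2 (1.25 ± 0.06), the transcription factor gene Bhlhe40 (0.94 ± 0.07), Lox (0.88 ± 0.05) and the integrin gene Itgb5 (0.87 ± 0.04). Markers of other cell types moved the same way. Of 16 fibroblast markers, 9 rose and 2 fell (median 0.29, adjusted p = 3.26e-06, and 0.0217 with an estimated correlation), with Dpt at 1.91 ± 0.06, Mfap5 at 1.16 ± 0.06 and Pdgfra at 1.12 ± 0.06. Of 14 pericyte and smooth muscle markers, 6 rose and 1 fell (median 0.18, adjusted p = 0.00202, and 0.0467 with an estimated correlation), with Cnn1 at 1.61 ± 0.07 and Mcam at 0.95 ± 0.04, while Rgs5 was the marker that fell.

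A further 5 lists passed with the preset correlation and not with an estimated one. The NRF2 oxidative stress list had 13 of 20 genes higher and 2 lower (median 0.20, adjusted p = 1.13e-05, but adjusted p = 0.0510 with an estimated correlation), among them Hmox1, heme oxygenase (1.05 ± 0.05), Osgin1 (0.93 ± 0.06) and Gclc, of glutathione synthesis (0.63 ± 0.05). The p53 list had 8 of 17 higher and 1 lower (median 0.19, adjusted p = 0.000141, but adjusted p = 0.0809 with an estimated correlation), such as Btg2, an antiproliferative gene (0.86 ± 0.05). The FOXO target list had 9 of 25 higher and 1 lower (median 0.12, adjusted p = 0.00590, but adjusted p = 0.252 with an estimated correlation), such as Txnip, an inhibitor of thioredoxin (1.01 ± 0.05), and Pik3ip1 (0.58 ± 0.04). Of 32 oxidative phosphorylation genes, 7 fell and none rose (median -0.10, adjusted p = 9.34e-05, but adjusted p = 0.193 with an estimated correlation). Its members Ndufb8, Atp5c1, Uqcrc2 and Atp5o lost their calls whichever mouse was left out (limma adjusted p 0.0503 to 0.193). The RTK-MAPK list had 8 of 22 higher and 3 lower (median 0.07, adjusted p = 0.0291, but adjusted p = 0.442 with an estimated correlation), with Ier3, an early response gene, at 1.16 ± 0.06 and Hbegf at 0.56 ± 0.06. Its adjusted p ran from 0.00990 to 0.0709 over the other camera settings, and passed 0.05 without mouse 1 (0.0572), mouse 3 (0.0609), control mouse 3 (0.0709), Pax7-ERD mouse 1 (0.0656) or Pax7-ERD mouse 2 (0.0537).

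Adjusted over the list alone, the higher and lower counts were 0 and 34 for G1/S, 0 and 39 for G2/M, 15 and 1 for hypoxia, 31 and 3 for extracellular matrix, 19 and 1 for TGF-beta, 11 and 2 for fibroblast markers and 8 and 2 for pericyte markers. They were 14 and 2 for NRF2, 11 and 1 for p53, 12 and 3 for FOXO targets, 0 and 8 for oxidative phosphorylation and 10 and 4 for RTK-MAPK. The muscle differentiation list did not pass (3 of 50 higher, 8 lower, median -0.03, adjusted p = 0.0844, range 0.0480 to 0.277 over the other camera settings, the lowest with a trended robust variance). The satellite cell identity list had 7 higher and 10 lower of 31 (adjusted p = 0.440), and differed in sign between median, mean and test. Cd34, a surface protein of quiescent satellite cells, rose within it (2.01 ± 0.06). The adjusted p of the other 10 lists lay between 0.0594 for the endothelial and Schwann markers and 0.772 for the leukocyte markers.

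limma called 4205 genes, 2114 higher and 2091 lower (1861 and 2587 with each array centred on its median), and 99 of them had an absolute log2 fold change of at least 1, of which 92 were higher. Without the mouse block 4283 genes were called, 4026 of them shared. Leaving out a whole mouse lowered the count to 1933, 1925 or 2532 for mice 1, 2 and 3. Camera called up to 10 lists on splits that mixed the groups, beside 12 on the real one.

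**Figure D2:**
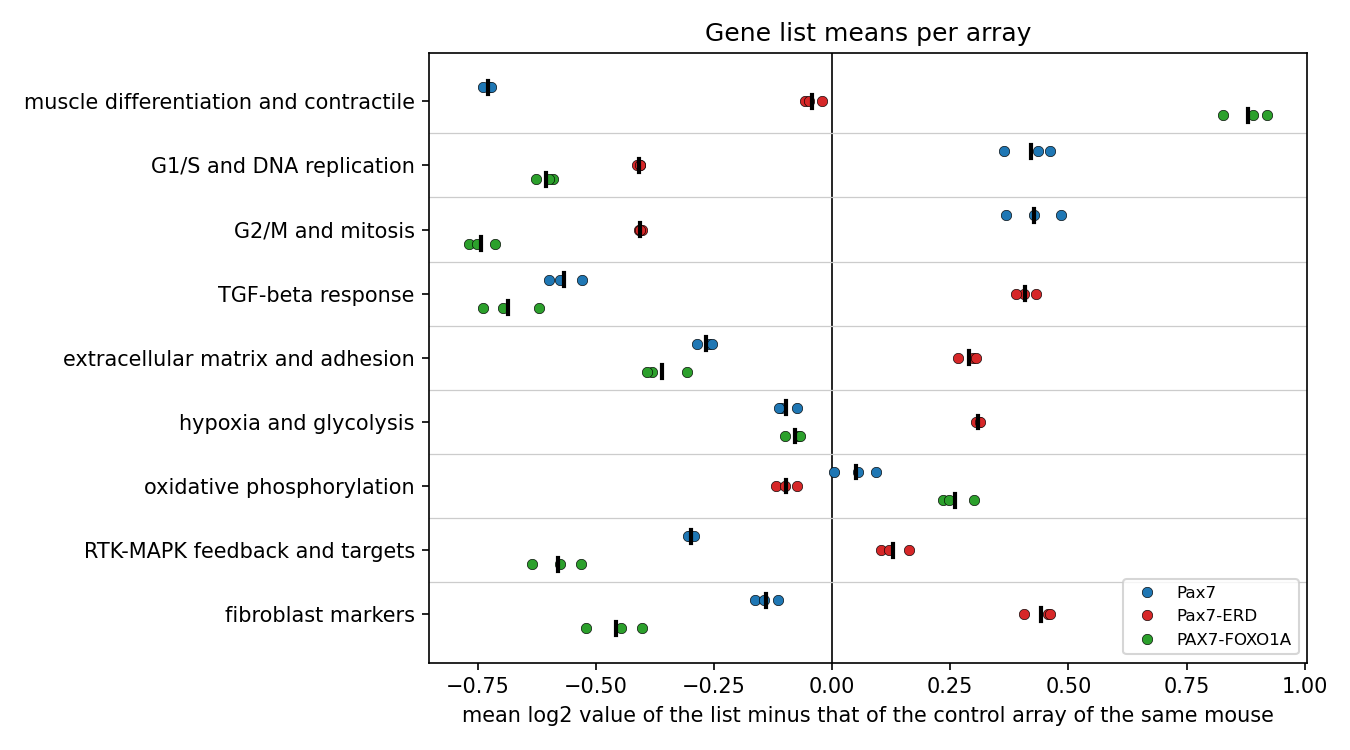
Mean log2 signal of 9 gene lists in each infected culture minus the same mouse's control culture, by construct, with dots for the mice and a tick for their mean (n = 3). The muscle differentiation mean lies below control with Pax7 and above it with PAX7-FOXO1A, and both cell cycle means lie above control with Pax7 and below it with the other constructs.

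PAX7-FOXO1A against control asks how myoblasts respond to the fusion construct. These cultures held more RNA of muscle differentiation and oxidative phosphorylation genes and less of cell cycle, TGF-beta, matrix and RTK-MAPK genes. Of these lists only muscle differentiation kept its call with the correlation estimated (adjusted p = 0.0413 with an estimated correlation), and the others gave adjusted p between 0.0798 and 0.126. Myog rose 1.64-fold (0.71 ± 0.07, adjusted p = 3.43e-05), Myf5 rose 1.61-fold (0.68 ± 0.07, adjusted p = 3.33e-05) and Fgfr4 rose 1.83-fold (0.87 ± 0.04, adjusted p = 1.92e-07). The largest increase was that of Lgr5 at 28.4-fold (4.83 ± 0.05, adjusted p = 2.03e-10). The largest decrease was that of Gzmd at 10.5-fold (-3.39 ± 0.08, adjusted p = 7.92e-09).

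The other highest genes were the calpain family gene Capn6 (4.54 ± 0.08), Dbpht2 (4.35 ± 0.07), the glypican gene Gpc3 (4.35 ± 0.07), Dbx1, a homeobox gene of neural progenitors (4.06 ± 0.09), the carboxypeptidase gene Cpm (3.999 ± 0.07), the kinase gene Nrk (3.62 ± 0.07) and Calb2, the calcium-binding protein calretinin (3.54 ± 0.10). The other lowest were Serpinb2 (-2.98 ± 0.06), Akr1c18 (-2.56 ± 0.11), the R-spondin receptor gene Lgr6 (-2.54 ± 0.04), Stmn2, a tubulin-binding protein of neurons (-2.45 ± 0.07), the cytokines Il11 (-2.41 ± 0.06) and Il6 (-2.38 ± 0.11), and the chemokine Cxcl14 (-2.29 ± 0.06). Id3 fell by 0.54 ± 0.08 (adjusted p = 0.000459), and Pax3 read -0.15 ± 0.06 (adjusted p = 0.0676). Myod1 rose by 0.12 ± 0.04 (adjusted p = 0.0321, range 0.000205 to 0.187), and that call ended in 10 of 17 alternatives.

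Of 50 muscle differentiation genes, 47 rose and none fell (median 0.74, adjusted p = 1.56e-26, and 0.0413 with an estimated correlation). Tmod1, which caps actin filaments (2.74 ± 0.05, and 0.425 in its other, dimmer row), the troponin gene Tnnc2 (1.84 ± 0.06), Myom1 (1.54 ± 0.04) and the glycogen phosphorylase gene Pygm (1.31 ± 0.04) were among them. Of 35 G1/S genes, 33 fell and 1 rose (median -0.67, adjusted p = 3.45e-15, but adjusted p = 0.0798 with an estimated correlation), with Ccne2 (-1.07 ± 0.06) and Tk1 (-0.87 ± 0.04) as examples. All 39 measured G2/M genes fell (median -0.78, adjusted p = 1.15e-21, but adjusted p = 0.0952 with an estimated correlation), including the mitotic kinase gene Ttk (-1.10 ± 0.05) and the kinesin gene Kif23 (-1.02 ± 0.05). Of 32 oxidative phosphorylation genes, 23 rose and none fell (median 0.25, adjusted p = 3.07e-08, but adjusted p = 0.126 with an estimated correlation), with the complex I subunit genes Ndufa9 (0.58 ± 0.04) and Ndufs3 (0.49 ± 0.04) among them. The satellite cell identity list had 16 of 31 higher and 8 lower (median 0.17, adjusted p = 0.0318, but adjusted p = 0.337 with an estimated correlation). Heyl, a Notch effector (0.83 ± 0.04), and Eya4 (0.75 ± 0.04) rose in it and Cd34 fell (-1.26 ± 0.06). Its adjusted p ran from 0.00878 to 0.121 over the other camera settings, passing 0.05 with the 6 arrays alone (0.0646) and without mouse 3 (0.121), control mouse 3 (0.0644) or PAX7-FOXO1A mouse 3 (0.0534).

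The RTK-MAPK list had 18 of 22 lower and 2 higher (median -0.54, adjusted p = 8.19e-08, but adjusted p = 0.126 with an estimated correlation), with Dusp5 (-1.67 ± 0.05), Hbegf (-1.67 ± 0.06), the ETS factor gene Etv4 (-1.13 ± 0.04) and the oncogene Myc (-1.12 ± 0.04). Of 21 TGF-beta response genes, 18 fell and 1 rose (median -0.67, adjusted p = 1.08e-09, but adjusted p = 0.126 with an estimated correlation), including Bhlhe40 (-1.57 ± 0.07), Timp3 (-1.54 ± 0.05) and Smad7, a feedback inhibitor of TGF-beta signalling (-1.26 ± 0.05). Of 40 matrix genes, 29 fell and 3 rose (median -0.29, adjusted p = 2.29e-07, but adjusted p = 0.126 with an estimated correlation). Tnc, tenascin C (-1.28 ± 0.04), and Fbln2 (-1.22 ± 0.04) fell, and the laminin gene Lama2 of the muscle basement membrane rose (1.13 ± 0.05). Fibroblast markers moved with these lists, 9 of 16 lower and 1 higher (median -0.27, adjusted p = 0.00217, but adjusted p = 0.0952 with an estimated correlation), with Mfap5 at -1.56 ± 0.06 and Pdgfra at -1.46 ± 0.06. The NRF2 list had 12 of 20 lower and 2 higher (median -0.21, adjusted p = 0.000460, but adjusted p = 0.126 with an estimated correlation), such as Gclm, of glutathione synthesis (-0.84 ± 0.05), and the quinone reductase gene Nqo1 (-0.69 ± 0.04). Adjusted over the list alone, the higher and lower counts were 48 and 0 for muscle differentiation, 19 and 9 for satellite cell identity, 1 and 19 for TGF-beta and 2 and 13 for NRF2, and those of the G1/S, G2/M, oxidative phosphorylation, RTK-MAPK, matrix and fibroblast lists equalled the counts over all genes.

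Of the 29 measured PAX-FOXO1 rhabdomyosarcoma genes, 13 rose and 7 fell, and the list did not pass (adjusted p = 0.0526, and 0.0383 without the mouse block, range 0.0281 to 0.114 over the other camera settings). Dcx, a microtubule protein of migrating neurons (2.67 ± 0.06), rose within it. The other 13 lists gave adjusted p between 0.0754 for BMP and Id genes, of which 4 rose and 11 fell, and 0.815 for the p53, interferon and pericyte lists. Those 3 lists differed in sign between median, mean and test. Single marker genes of other cell types still moved, among them Tek of endothelial cells (2.17 ± 0.09), Cd36 of adipocytes (1.62 ± 0.07), Erbb3 of Schwann cells (1.32 ± 0.04) and Cd53 of leukocytes (-1.59 ± 0.05).

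limma called 8344 genes, 3800 higher and 4544 lower, and 622 of them had an absolute log2 fold change of at least 1, of which 393 were higher and 229 lower. Without the mouse block 8316 genes were called, 8094 of them shared. Camera called up to 10 lists on splits that mixed the groups, as many as on the real one.

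Pax7 against Pax7-ERD sets the construct beside its dominant-negative form. Myf5 was 8.29-fold higher with Pax7 (3.05 ± 0.07, adjusted p = 3.29e-09) and Fgfr4 was 3.48-fold higher (1.80 ± 0.04, adjusted p = 2.33e-09). Vat1l (4.34 ± 0.06), Olfr1372-ps1 (4.18 ± 0.13), Pde1a (4.02 ± 0.06), Mme (3.84 ± 0.06) and Lix1 (3.83 ± 0.09) were the genes highest with Pax7 relative to Pax7-ERD. Gzmd (-3.94 ± 0.08), Plscr2 (-3.90 ± 0.07), Nt5e (-3.85 ± 0.05), Anxa8 (-3.80 ± 0.09) and Cd34 (-3.68 ± 0.06) were those lowest with Pax7 relative to Pax7-ERD. For Gzmd the difference came from its fall with Pax7 (-3.79 against control), as with Pax7-ERD it read 0.15 ± 0.08 against control (limma adjusted p = 0.259). The Pax7 row itself was 0.34 ± 0.05 higher with Pax7 (adjusted p = 0.00037). Foxo1 was higher with Pax7 (0.59 ± 0.04) and Myog lower (-0.45 ± 0.07, adjusted p = 0.000774), while Pax3 (-0.02 ± 0.06, adjusted p = 0.866), Myod1 (0.03 ± 0.04, adjusted p = 0.548) and Id3 (0.15 ± 0.08, adjusted p = 0.191) did not pass.

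All 35 G1/S genes (median 0.84, adjusted p = 2.21e-22) and all 39 G2/M genes (median 0.84, adjusted p = 6.16e-26) were higher with Pax7, with Ccne1 at 1.15 ± 0.04 and Nuf2 at 1.15 ± 0.04. Of 50 muscle differentiation genes, 45 were lower and 3 higher with Pax7 (median -0.71, adjusted p = 1.42e-20), such as Myh1 (-1.63 ± 0.05). Of 21 TGF-beta genes, 20 were lower (median -0.78, adjusted p = 2.72e-15), such as Ltbp2 (-2.54 ± 0.06), and of 40 matrix genes 36 were lower and 1 higher (median -0.55, adjusted p = 1.26e-16), such as Fbln2 (-1.82 ± 0.04) and the fibronectin receptor gene Itga5 (-1.16 ± 0.05). Fibroblast markers moved with them (11 of 16 lower, 1 higher, adjusted p = 2.33e-05), such as Mfap5 (-2.51 ± 0.06), and so did pericyte markers (11 of 14 lower, 1 higher, adjusted p = 1.46e-06), such as Cnn1 (-2.80 ± 0.07). The hypoxia list had 16 of 24 lower and 3 higher (adjusted p = 1.96e-05), such as Vegfa (-1.53 ± 0.04). These 8 lists also passed with an estimated correlation (adjusted p between 0.0199 and 0.0302). The RTK-MAPK list had 15 of 22 lower and 5 higher (adjusted p = 0.000136, but adjusted p = 0.266 with an estimated correlation), such as Hbegf (-2.09 ± 0.06).

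The FOXO target list had 13 of 25 lower and 2 higher (adjusted p = 0.00529, but adjusted p = 0.266 with an estimated correlation), such as Cited2 (-0.84 ± 0.04) and the kinase gene Pdk4 (-0.85 ± 0.04). The oxidative phosphorylation list had 17 of 32 higher and 1 lower (adjusted p = 0.000145, but adjusted p = 0.256 with an estimated correlation), such as Ndufa4 (0.41 ± 0.05). Adjusted over the list alone, the higher and lower counts were 2 and 14 for FOXO targets, 3 and 17 for hypoxia and 5 and 16 for RTK-MAPK, and equalled those over all genes for the other 8 lists. The satellite cell identity, BMP, p53 and Wnt lists, none of which passed, differed in sign between median, mean and test. limma called 7549 genes, 3879 higher and 3670 lower with Pax7, and 721 had an absolute log2 fold change of at least 1, of which 294 were higher and 427 lower. Without the mouse block 7554 genes were called, 7341 of them shared. Camera called 11 lists, and a split that mixed the groups called 11 as well.

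PAX7-FOXO1A against Pax7 sets the fusion beside the unfused factor. All 50 muscle differentiation genes were higher with PAX7-FOXO1A (median 1.61, adjusted p = 2.80e-33, and 0.0228 with an estimated correlation). Myf6, a regulator of muscle fibre genes, was 11.5-fold higher (3.52 ± 0.12, adjusted p = 1.33e-08), Myog 2.83-fold higher (1.501 ± 0.07, adjusted p = 1.49e-07) and Myom1 6.55-fold higher (2.71 ± 0.04). Myf5 was 2.56-fold lower (-1.35 ± 0.07, adjusted p = 2.15e-07). Fgfr4 read -0.02 ± 0.04 (adjusted p = 0.707), a difference within its error. Dbpht2 (4.20 ± 0.07), Gpc3 (4.05 ± 0.07), Dbx1 (3.89 ± 0.09), Armh4 (3.599 ± 0.12), the lubricin gene Prg4 (3.57 ± 0.09), Cga, the shared alpha subunit of glycoprotein hormones (3.43 ± 0.08), and Calb2 (3.36 ± 0.10) completed the 8 highest. The 8 lowest were Itga2 (-4.49 ± 0.05), Zfp185 (-3.25 ± 0.05), the fatty acid elongase gene Elovl7 (-3.08 ± 0.10), Bmp4 (-3.00 ± 0.08), Tshr (-2.84 ± 0.06), the desmosome gene Dsp (-2.69 ± 0.08), Nrsn1 (-2.45 ± 0.09) and the glucose transporter gene Slc2a3 (-2.42 ± 0.06). Myod1 was higher (0.23 ± 0.04, adjusted p = 0.000557), and Pax3 (-0.26 ± 0.06), Id3 (-0.58 ± 0.08) and Foxo1 (-0.44 ± 0.04) were lower.

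Of 35 G1/S genes, 34 were lower with the fusion and 1 higher (median -1.12, adjusted p = 1.44e-18, and 0.0488 with an estimated correlation), such as Tk1 (-1.55 ± 0.04) and the thymidylate synthase gene Tyms (-1.44 ± 0.05). All 39 G2/M genes were lower (median -1.20, adjusted p = 3.09e-24, but adjusted p = 0.0722 with an estimated correlation), such as Ttk (-1.53 ± 0.05). The oxidative phosphorylation list had 22 of 32 higher (adjusted p = 9.70e-06, but adjusted p = 0.192 with an estimated correlation), such as Ndufa9 (0.45 ± 0.04). The neural list had 19 of 40 higher and 8 lower (adjusted p = 0.0127, but adjusted p = 0.188 with an estimated correlation), with Dcx at 2.80 ± 0.06 and the semaphorin receptor gene Plxna2 at 2.08 ± 0.06. The NRF2 list had 14 of 20 lower and 3 higher (adjusted p = 0.00279, but adjusted p = 0.188 with an estimated correlation), such as Nqo1 (-1.44 ± 0.04). The RTK-MAPK list had 15 of 22 lower and 3 higher (adjusted p = 0.00362, but adjusted p = 0.427 with an estimated correlation), such as Etv4 (-1.63 ± 0.04), while Spry1, a feedback inhibitor of this signalling, was higher (1.13 ± 0.05).

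Pericyte and smooth muscle markers moved with the muscle genes, 11 of 14 higher and 1 lower (adjusted p = 0.00185, but adjusted p = 0.0722 with an estimated correlation), including Abcc9 (2.70 ± 0.05) and the muscle intermediate filament gene Des (0.50 ± 0.04). Of 16 fibroblast markers, 9 were lower and 1 higher, such as Pdgfra (-1.54 ± 0.06), with adjusted p = 0.0444 and adjusted p = 0.188 with an estimated correlation. This call ended with the 6 arrays alone (0.0568), with quantile normalization (0.0520), with dim genes left out (0.0567) and without mouse 2 (0.103) or PAX7-FOXO1A mouse 2 (0.0938), in a range of 0.0189 to 0.103 over the other camera settings. Adjusted over the list alone, the higher and lower counts were 4 and 15 for NRF2, 25 and 0 for oxidative phosphorylation and 2 and 9 for fibroblast markers, and equalled those over all genes for the other 6 lists. The hypoxia list, which did not pass, differed in sign between median, mean and test. limma called 9053 genes, 4107 higher and 4946 lower with the fusion, and 1118 had an absolute log2 fold change of at least 1, of which 639 were higher and 479 lower. Without the mouse block 9038 genes were called, 8808 of them shared. Camera called 9 lists, and a split that mixed the groups called 10.

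The calls against control were then set side by side. Pax7 and Pax7-ERD shared 2372 called genes, of which 1559 moved in opposite directions and 813 in the same one, where independent lists would share 583.6 and 583.8. Cd34 (-1.67 ± 0.06 with Pax7 and 2.01 ± 0.06 with Pax7-ERD), Plscr2 (-1.81 ± 0.07 and 2.09 ± 0.07), Ltbp2 and Cnn1 moved apart. Gpnmb, a membrane glycoprotein (2.87 ± 0.05 and 1.37 ± 0.05), Rgs2 (2.36 ± 0.07 and 1.40 ± 0.07) and the keratin gene Krt18 (1.29 ± 0.09 and 1.60 ± 0.09) rose with both, and Gal and Stmn2 fell with both. Pax7 and PAX7-FOXO1A shared 4026 genes, 1868 in the same direction and 2158 in opposite ones, where independent lists would share 1155.5 and 1160.9. Mstn, the inhibitor of muscle growth myostatin, rose with both (2.91 ± 0.07 and 2.91 ± 0.07), as did Lgr5 and Capn6, and Gzmd, Il11, Serpinb2 and Akr1c18 fell with both. The myosin gene Myh4 (-1.15 ± 0.08 and 1.54 ± 0.08), Myom3 (-1.15 ± 0.05 and 1.28 ± 0.05) and the ciliary neurotrophic factor receptor gene Cntfr (1.18 ± 0.06 and -1.19 ± 0.06) moved apart.

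Pax7-ERD and PAX7-FOXO1A shared 3082 genes, 1550 in the same direction and 1532 in opposite ones, where independent lists would share 879.5 and 880.3. The endothelin gene Edn1 (1.16 ± 0.08 and 0.99 ± 0.08) and the cholesterol exporter gene Abca1 (1.49 ± 0.06 and 0.82 ± 0.06) rose with both. The prostaglandin synthase gene Ptges (1.29 ± 0.07 and -1.37 ± 0.07) and the prostaglandin transporter gene Slco2a1 (1.52 ± 0.06 and -1.20 ± 0.06) rose with Pax7-ERD and fell with the fusion. The 3 comparisons share the 3 control arrays, which are too few to be divided between them, so part of the excess in the same direction may come from the shared controls. The count for independent lists also treats all 19938 genes, dim ones included, as equally likely to be called. Shared calls exceeded it in both directions for each pair, so the excess alone does not show shared regulation. In 20 simulations every array, controls included, was drawn with no change, and the groups shared the simulated controls. No gene was called in both comparisons of a pair there, but with no change added hardly any gene can be called at all. That count therefore does not measure how many shared calls the controls add. The simulated covariances of the fold changes, which do reflect shared controls, were 0.00307, 0.00307 and 0.00306. The measured covariances were -0.0108 for Pax7 with Pax7-ERD, 0.0130 for Pax7 with PAX7-FOXO1A and -0.00460 for Pax7-ERD with PAX7-FOXO1A. Among changes of at least 1 log2 unit the 3 pairs shared 5, 106 and 0 genes in the same direction and 20, 32 and 19 in opposite ones.

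**Figure D3:**
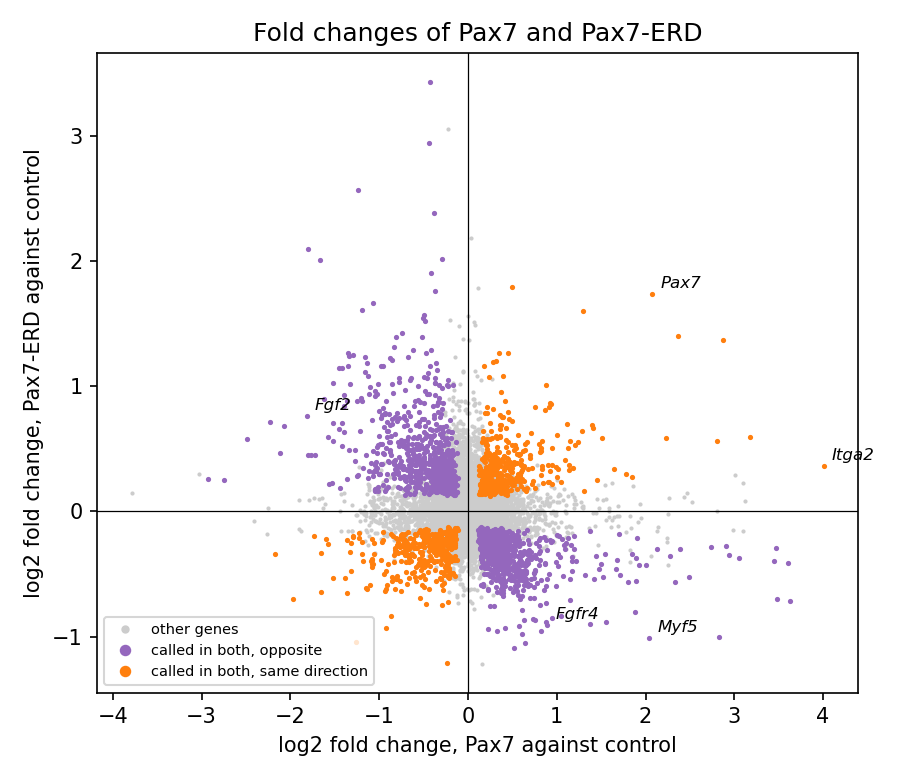
Log2 fold change against control of each gene with Pax7 and with Pax7-ERD, with genes called in both comparisons coloured by whether they moved in opposite directions (1559 genes) or in the same one (813 genes). The genes in opposite directions lie to the upper left and lower right of the origin.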

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

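The tests of cell types, probes, signal range and the inverse construct in this part were chosen only after the results they concern were seen. No group has over 3 arrays, so arrays were not tested for lying far from their group.

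Rows of the table that list no gene were left out of the comparisons, and some of them were raised over control. At least 1 log2 unit above control and called were 15 such rows with Pax7, 4 with Pax7-ERD and 85 with PAX7-FOXO1A, of 12146 (22, 6 and 78 were as far below). Row 10464030 read 9.79 with Pax7 and 7.24 in control, and row 10429564 read 13.07 with Pax7-ERD and 11.14 in control.

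Fibroblast markers rose with Pax7-ERD (9 of 16 higher and 2 lower). With Pax7, 7 of 16 were lower and 2 higher, a call (adjusted p = 0.0378) that ended with an estimated correlation (0.135), without mouse 3 (0.0519), without control mouse 2 (0.0546) and without Pax7 mouse 1 (0.0520). In control, 9 of the 16 measured markers had a mean above the brightness value (log2 7.21), which is not a limit of detection. If fibroblasts were more numerous with Pax7-ERD, their abundant transcripts would rise together, yet Ccl11 read -0.198 ± 0.0568 (SE) while Mfap5 rose by 1.16 and Pdgfra by 1.12. Every other marker of this set was also called higher, namely Gsn (0.757), Cd248 (0.714), Thy1 (0.548), Dcn (0.401), Osr1 (0.350) and Col3a1 (0.195). If fibroblasts were fewer with Pax7, all would fall, yet Gsn rose by 0.389 ± 0.0498 while Mfap5 fell (-1.35). Cd248 (-0.547), Col3a1 (-0.401), Dcn (-0.382), Osr1 (-0.274) and Ccl11 (-0.241) were also called lower, and Thy1 and Pdgfra were not called. The exceptions argue only against a changed share of fibroblasts as the sole cause for every marker. In each comparison they rest on 1 marker picked after the values were seen, while most of the others moved as a changed share would move them. How large a part a changed share had in either comparison stays open. A response to TGF-beta may contribute with Pax7-ERD, since 18 of 21 TGF-beta genes, none of them a fibroblast marker of the list, were higher, but this hypothesis was found and tested on the same arrays.

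Gzmd fell with Pax7 and PAX7-FOXO1A, and Gzme fell with Pax7. Loss of leukocytes that carry both would lower both with PAX7-FOXO1A, but Gzme read -0.18 ± 0.14 (SE, adjusted p = 0.364) beside -3.39 ± 0.08 for Gzmd, which argues against it. Loss of cells that carry Gzmd without Gzme stays open there, as the leukocyte markers Cd53 (-1.59 ± 0.05) and Laptm5 (-0.50 ± 0.04) also fell and Cd68 read -0.22 ± 0.08 (adjusted p = 0.0609). Probes shared between the genes are argued against as a single common signal, since their changes differed by -3.21 ± 0.162 in that comparison. With Pax7, loss of leukocytes cannot be told apart from regulation in the myoblasts, which was not tested, because only 3 of 17 leukocyte markers were above the brightness value (median -0.42: Laptm5 and Cd53 lower, Cd68 higher).

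The muscle differentiation list fell with Pax7 and rose with PAX7-FOXO1A but did not pass with Pax7-ERD. Signal too bright to rise further is argued against, since the 20 members at log2 12 or more in control rose by a median of 0.489 with PAX7-FOXO1A, 18 of them called. Pax7-ERD as the plain inverse of Pax7 would raise the list by a large part of its fall (-0.82), yet the median was -0.0333, so this reading is argued against for this list. The explanation stays open.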

How the results depend on the processing

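All alternatives here were planned, and none was added later. Over all alternatives, 14 of 486 values of single named genes changed their call in 67 of 8253 alternative values (64 lost, 3 gained, 0 reversed), and 81 of 120 single list tests changed in 137 of 2280 (47 lost, 88 gained, 2 reversed). The 2 reversed were the BMP list (adjusted p = 0.0212, range 0.0212 to 0.822) and the Wnt list (adjusted p = 0.00716, range 0.00716 to 0.996) with Pax7, which fry called higher while camera leaned lower. Their means were 0.14 and 0.13, Bmp4 and Lgr5 rose most in them, and the cause was not tested. Without the mouse block 0 named genes changed and 1 list, PAX-FOXO1 with PAX7-FOXO1A, was gained. Apart from the genes fixed in advance, named genes were picked by large fold change or low p on these same arrays. Their stability therefore does not speak for the other called genes.

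The 5 counts of genes stayed within 1.5 times of their value in every alternative except a minimum log2 fold change of 1, which by construction calls fewer (371, 99, 622, 721 and 1118), and leaving out mouse 1 or 2 for Pax7 and mouse 1, 2 or 3 for Pax7-ERD against control, which takes 4 arrays away. Leaving out a mouse or an array gave 3553 to 4903 genes for Pax7, 1925 to 3261 for Pax7-ERD and 6244 to 7510 for PAX7-FOXO1A, 5699 to 7059 for Pax7 against Pax7-ERD and 7345 to 8679 for PAX7-FOXO1A against Pax7. With no mouse block, shared calls in the same and opposite directions were 840 and 1599 for Pax7 with Pax7-ERD, 1870 and 2184 for Pax7 with PAX7-FOXO1A, and 1572 and 1591 for Pax7-ERD with PAX7-FOXO1A, and camera called 11 lists instead of 10 for PAX7-FOXO1A against control and as many as with it in the other comparisons. Shared calls at a minimum of 1, same and opposite, were 5 and 20 for Pax7 with Pax7-ERD, 106 and 32 for Pax7 with PAX7-FOXO1A, and 0 and 19 for Pax7-ERD with PAX7-FOXO1A. With a mouse or array left out they ran over 289 to 767 and 725 to 1457, over 1070 to 1722 and 1214 to 2000, and over 606 to 1392 and 729 to 1422. Without mouse 1, 2 and 3 the Pax7 and Pax7-ERD counts were 298, 289 and 448 in the same direction and 748, 725 and 924 in opposite ones, and without control mouse 1 or 2 the same-direction count was 518 or 535. For Pax7 with PAX7-FOXO1A they were 1070 and 1146 in the same direction without mouse 1 or 2, and 1282, 1214 and 1408 in opposite ones without mouse 1, 2 or 3. For Pax7-ERD with PAX7-FOXO1A they were 606, 622 and 874 in the same direction and 729, 735 and 955 in opposite ones, and 979 in the same direction without control mouse 1.

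An estimated correlation between genes called 3 lists for Pax7, 7 for Pax7-ERD, 1 for PAX7-FOXO1A and 2 for PAX7-FOXO1A against Pax7. The test fry, which asks whether genes move without comparing them with others, called 19, 21 and 21 lists against control, 20 for Pax7 against Pax7-ERD and 21 for PAX7-FOXO1A against Pax7. Trended and robust variance called 14 for PAX7-FOXO1A against Pax7, and the cause was not tested. Leaving out mice or arrays gave 8 to 11, 11 to 13, 9 to 11, 11 to 12 and 8 to 12 lists in the 5 comparisons. Signal over background was not measured, and the number of arrays limits the precision.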

Other observations

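The gene families and their examples were chosen after their values were seen, and the splits were planned. No set test was run on these families, and a changed share of other cell types was not excluded as a source of their changes. Marker lists of other cells moved too, with 10 of 14 pericyte markers lower with Pax7 and 6 higher with Pax7-ERD, and 9 of 16 fibroblast markers higher with Pax7-ERD and 9 lower with PAX7-FOXO1A. The fibroblast call by camera with PAX7-FOXO1A ended with an estimated correlation (adjusted p = 0.0952). The pericyte list also holds genes of muscle cells, such as Des, so its movement need not reflect other cells. Ccl11 is in both the chemokine family and the fibroblast list. Members of the families were kept where the mean over all 12 arrays reached the brightness value (log2 7.21), whatever the group. Over all 19938 genes, 27.8% were called with Pax7, 21.1% with Pax7-ERD and 41.9% with PAX7-FOXO1A, each against control. Those shares include dim genes, which the families leave out, so the family counts are not directly comparable with them. Of 12 chemokine ligand genes, which attract leukocytes, 8 fell and none rose with Pax7, 5 rose and 2 fell with Pax7-ERD, and 7 fell and 1 rose with PAX7-FOXO1A. Ccl7 read -0.91 ± 0.05 (SE, n = 3) with Pax7, 0.64 ± 0.05 with Pax7-ERD and -1.82 ± 0.05 with PAX7-FOXO1A, and Cx3cl1 read -0.78 ± 0.07, 1.03 ± 0.07 and -1.28 ± 0.07. Cxcl13 fell with Pax7 (-1.13 ± 0.10) and rose with PAX7-FOXO1A (1.01 ± 0.10). Of 10 genes of secreted fibroblast growth factors, 8 fell and none rose with Pax7, 5 rose and 2 fell with Pax7-ERD, and 4 rose and 3 fell with PAX7-FOXO1A (4 and 4 with quantile normalization). Fgf2, a mitogen of satellite cells, read -1.82 ± 0.05, 0.76 ± 0.05 and -2.14 ± 0.05, while Fgf9 read -1.03 ± 0.06, 0.35 ± 0.06 and 0.59 ± 0.06.

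Of 20 integrin subunit genes, which encode receptors for matrix proteins and other cells, 13 fell and 2 rose with Pax7, 13 rose and 2 fell with Pax7-ERD, and 11 fell and 5 rose with PAX7-FOXO1A. Itgb8 read -1.39 ± 0.06, 0.63 ± 0.06 and -0.69 ± 0.06, Itga11 read -0.74 ± 0.07, 1.43 ± 0.07 and -0.29 ± 0.07, and Itga4 read -0.79 ± 0.05 with Pax7 and 1.70 ± 0.05 with PAX7-FOXO1A. Itga2 rose with Pax7 (4.005 ± 0.05) against the direction of most of its family. Quantile normalization and median centring moved each count of these families by at most 1 gene, and the majority direction differed only for the fibroblast growth factors with PAX7-FOXO1A under quantile normalization.

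Each comparison of 3 arrays with 3 has 10 splits, so no share under 0.1 can be reached, and the real split was 1 of them. The real splits called 5535 genes for Pax7, 4205 for Pax7-ERD and 8344 for PAX7-FOXO1A against control, 7549 for Pax7 against Pax7-ERD and 9053 for PAX7-FOXO1A against Pax7, and the highest other splits called 0, 1, 0, 0 and 0. For lists, the real splits called 9, 12, 10, 11 and 9 and the highest other splits 8, 10, 10, 11 and 10, with 1, 1, 2, 2 and 2 splits as large, the real one included. The other splits set 2 arrays of a group against 1, so part of the construct effect remains in them. List calls with a preset correlation arise on them too. The construct difference also enters the residual variance of these splits, which holds gene calls down. Their low gene counts therefore do not measure how many calls arise by chance.

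For shared calls, 100 draws of group labels over the 9 arrays of each pair were made, and 3, 3 and 1 of them gave as many genes as the real labels, the real ones included. The median of the other draws was 0 shared genes, so the draws show that the groups differ and do not test whether the calls of a pair agree beyond chance. The real counts were 2372 for Pax7 with Pax7-ERD, 4026 for Pax7 with PAX7-FOXO1A and 3082 for Pax7-ERD with PAX7-FOXO1A, and the highest other draws gave 3291, 4593 and 389. The 2 other draws as large in each of the first pairs kept the 3 arrays of a construct whole as the shared reference, which points to the structure of the groups.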
